A study of Oryza sativa with 6 samples.

How the data were processed

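Small RNA was sequenced from germinating seeds of the rice cultivar Kasalath kept at 25 °C ("normal") or at 35 °C ("hot"), with 3 libraries per temperature. Per the labels' protocols, 40 seeds were placed on damp tissue, 5 to a dish, with 4 dishes at each temperature, and the dishes were kept damp up to day 8. The labels give the age as 5 days after germination, and how the 2 times relate is not given in the sources used here. Small RNA was isolated with a mirVana kit and made into libraries with the NEBNext small RNA set and bead size selection, per the labels' protocols, and read on a MiSeq, per the series' design text. That text calls the libraries of a temperature biological triplicates. How the dishes map to the libraries is not given in the sources used here.

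The deposited table has 641 named miRNAs with, per the file headers, a raw expression and a normalised expression column for each library. The raw columns hold whole counts and were taken as the authors' read counts per miRNA name. The matching tool, the miRNA database release, the genome build and the meaning of the bracketed 0 after each name are not given in the sources used here. No sequences or genome positions were used here, so items are named as in the table. The deposited normalised value is the count divided by 1 total per library, on a fixed scale, and it was used only to recover that total, from the rows with a count above 20. What the total counts is not stated in the headers. All per-sample columns were mapped to libraries through the labels' sample descriptions.

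The same reads were entered under several names. Of the 641 names, 306 belong to sets whose counts are identical or exact whole multiples of each other within a family in all 6 libraries. The table holds 412 distinct count patterns in 113 families. A column sum is therefore not a number of sequenced reads, names of a family are not independent measurements, and an adjusted p over names treats repeated reads as separate tests. Multiplied counts also look more precise than the reads behind them. Rows a few counts away from a multiple of each other (near-multiples) count as distinct patterns. Patterns of a family are therefore not independent measurements either.

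Column sums ran from 136294 (normal 2) to 377473 (hot 3), and library totals from 157488 (hot 1) to 275549 (normal 3). These depths leave many names with few counts: 253 names and 32 families passed the filter. Intervals on low counts cover counting error only, since they pool the 3 libraries of a group and leave out the spread between libraries. The reads also carry no stated molecular identifiers, so each count was taken as a separate molecule.

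Counts were analysed with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F test, group as the only term, all 6 libraries in 1 fit). Benjamini-Hochberg adjusted p under 0.05 was the threshold. The standard error of a log2 fold change is its size over the square root of F. CPM values are counts relative to the TMM-scaled column sum. The family of a name is the number after "mir", and a family value is the sum of its names with identical rows added once. Exact multiples that are not identical stay in that sum, so abundant names weigh more. Fixed miRNA lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided, lists of at least 3 tested names). They were tested again with an estimated correlation and with fry. Composition measures were compared by an exact two-sided permutation test of the group means, whose smallest p with 3 against 3 libraries is 0.1, so it cannot pass 0.05. The Benjamini-Hochberg step there ran over 7 measures.

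Libraries of a group differed in all pairs by more than the counting error of the entered counts, with a chi-square per degree of freedom from 5.128 to 23.2 over distinct patterns, so none was a copy of another. Near-multiples left in these patterns raise that value. The labels name no batch.

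The names in the text follow a rule fixed before the data were examined: up to 15 names higher and 15 lower past the threshold by size of change, the 10 most abundant names, the 2 most abundant of each list, and up to 10 families per direction. All other names in the text and figures were chosen after their values were seen. The tests, lists and most alternatives were fixed at the same point. Added after seeing the data were scaling by the deposited library totals, 1 row per distinct count pattern (the smallest of each set), leaving out miR156, and family sums over distinct patterns or over all names. Alternatives meant for normalised values (other pseudocounts, a filter on the mean) were not run, because counts were present. Shares by sequence length or first base were not computed. A list of names with a prefix of another species was not tested, since the names carry no prefix.

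The scripts were tested on simulated counts drawn from the means and spread of these libraries. For single names, 53.8% of changes of 2-fold and 71.4% of changes of 4-fold were recovered among 242 names tested, and 1 of 188 unchanged names was called. For families, 1 of 3 changes of 2-fold and 2 of 4 changes of 4-fold were recovered among 31 tested. With no change simulated, a fixed dispersion of 0.09 and exact multiples repeated over names as in the table, 3 of 20 simulations gave a call and the highest number was 6. Names in the simulations with changes, and distinct patterns in those without, were drawn independently. Near-multiples in the table are not independent, so more false calls may occur together than these simulations show. DESeq2 1.42.0 and limma-voom were run as other tests.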

Results

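Small RNA of germinating rice seeds (cultivar Kasalath, an aus-type rice) was compared between 3 libraries from seeds at 25 °C and 3 from seeds at 35 °C, to find miRNAs whose level differs at high temperature during germination. The deposited counts summed to 147986, 136294 and 203192 in normal libraries 1 to 3 and to 169694, 330009 and 377473 in hot libraries 1 to 3. The library totals behind the deposited normalised values were 264112, 250255 and 275549 in the normal libraries and 157488, 240428 and 243885 in the hot libraries. The sums exceeded the totals in all 3 hot libraries. Between 425 and 522 of the 641 names had a count above 0 in a library.

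Names of the miR396 family, which targets growth-regulating factor transcripts, were higher in the hot libraries. Of 21 miR396 names tested, 14 rose, by 0.94 to 2.30 on the log2 scale, and none was called lower. Of the other 7, mir396f-5p had 1.07 (adjusted p = 0.0871, and called at 2.005 with the deposited library totals), mir396g -1.44 (45, 24 and 39 against 20, 18 and 22 counts, adjusted p = 0.0675) and mir396h -1.12 (adjusted p = 0.0951), all 3 named after their values were seen. The 4 tested 3p names, described after their values were seen, had 0.01 (mir396a-3p), -0.04 (mir396b-3p), 0.32 (mir396c-3p) and 0.01 (mir396d-3p). The name mir396a went from 2202 ± 286.5 to 8184 ± 1446 CPM (SD, n = 3 each), a log2 fold change of 1.89 (SE 0.16, adjusted p = 0.00276). The name mir396b rose from 3467 ± 873.1 to 15200 ± 5646 CPM, a log2 fold change of 2.13. The names mir396f and mir396-5p had the highest fitted change of the family, 2.30 (SE 0.44 for mir396f), and mir396d, the most abundant by summed counts, had 0.94. The others past the threshold within the named set were mir396c-5p (2.17), mir396d-5p and mir396i-5p (1.70 each, identical rows), mir396c (1.51), mir396e (1.22), mir396 (1.21) and mir396e-5p (1.09). All 14 were also called with the deposited library totals. Without normal library 2 the calls of mir396f and mir396-5p, the same reads, were lost.

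Low-count names rose as well. The miR398 names, of a family that targets copper/zinc superoxide dismutase transcripts, had 0, 0 and 7 counts in the normal libraries and 21, 70 and 49 in the hot libraries under mir398b (adjusted p = 0.0368). The rows mir398a and mir398c are exact fractions of the same reads. In the smallest row of that set, 1 count in the normal libraries stood against 20 in the hot libraries, a ratio of 12.4 after scaling with an exact binomial 95% interval of 1.98 to 513. With 1 row per distinct pattern that row did not pass the filter and was not tested. The call of mir398b was lost with DESeq2 size factors, without the miR156 names and without normal library 1, normal library 2, hot library 2 or hot library 3. For mir393b-3p, counts were 2, 2 and 2 against 14, 52 and 26 (log2 fold change 3.15, SE 0.60, adjusted p = 0.0119). The smallest row of its set, mir393a-3p, held 3 against 46 counts, a ratio of 9.49 (exact binomial 95% interval 3.05 to 47.7). The row mir393b-3p is 2 times that row. With 1 row per distinct pattern mir393a-3p did not pass the filter, so this rise was not tested there. The other tested miR393 name, mir393a, with 0, 0 and 13 against 13, 42 and 13 counts, was not called (adjusted p = 0.229), nor was the miR393 sum (adjusted p = 0.0978).

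Names of 9 families were lower in the hot libraries under TMM scaling. The miR159 family, which targets GAMYB transcription factor transcripts, had 11 of 16 tested names lower, by -0.86 to -1.57. The name mir159a went from 11120 ± 2361 to 4784 ± 668 CPM (log2 fold change -1.22, SE 0.17, adjusted p = 0.00337). The rows mir159b-3p.1, mir159f-3p, mir159j-3p and mir159k-3p are identical and had the greatest fitted fall in the family, -1.57 (SE 0.19). Next came mir159d (-1.50), mir159b-3p (-1.35), mir159a-1 (-1.35), mir159b (-1.32) and mir159a-3p (-1.20). With the deposited library totals none of the 11 was called, and 1 had a positive value. Without the miR156 names mir159a, mir159a-3p and mir159 were not called, and the call of mir159 was lost in 10 of 18 settings.

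Among called names, the greatest fitted falls were in low-count names of the lineage restricted list. That list holds every family outside the list of families conserved across flowering plants. The name mir5504 had 34, 36 and 29 counts in the normal libraries and 6, 6 and 14 in the hot libraries (log2 fold change -2.67, SE 0.47, adjusted p = 0.00889). The name mir5794 had a log2 fold change of -2.13 (adjusted p = 0.00544) and mir3630-3p of -2.22 (adjusted p = 0.0242). The identical rows mir1861h and mir1861j had -2.38 (SE 0.66, adjusted p = 0.0433), with 19, 28 and 15 against 1, 10 and 11 counts. Of these only mir5504 was called with the library totals, where its log2 fold change was -1.63. The call of mir3630-3p was also lost without the miR156 names and without normal library 1, normal library 2 or hot library 3, and that of mir1861h with DESeq2 size factors, without a filter, in limma-voom, without the miR156 names and without normal library 1, normal library 2, hot library 2 or hot library 3.

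Smaller falls under TMM covered 8 of 35 miR166 names, 8 of 21 miR167 names and all 7 miR319 names tested, families that target homeodomain-leucine zipper, auxin response factor and TCP transcription factor transcripts. Their log2 fold changes were -0.34 to -0.38, -0.42 to -0.71 and -0.77 to -0.92, and all of these values were positive and not called with the library totals. None of the 23 calls was kept without a filter, without the miR156 names or without normal library 2, and with DESeq2 size factors only mir319b and mir319b-3p were. The call of mir167c was lost in 12 of 18 settings, that of mir167e in 14 and that of mir166g in 12. These 3 families were described after their counts were seen, apart from mir167c.

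The 10 most abundant names were all of miR156, which targets SPL transcription factor transcripts. The most abundant, mir156a, had 89110 ± 8275 CPM in the normal and 102900 ± 809.4 in the hot libraries (log2 fold change 0.21, SE 0.08, adjusted p = 0.0873). The names mir156c, mir156d, mir156e, mir156f, mir156g and mir156b-5p had fitted changes of 0.21 as well, mir156b had 0.20 and mir156f-5p 0.17, none past the threshold. Of the 10 only mir156 was called, at -0.79 (SE 0.08, adjusted p = 0.00276), and its value turned to 0.19, not called, with the library totals. Its counts were 16 times those of mir156s in all 3 normal libraries and 8 times in all 3 hot libraries (tolerance 0.1). Over the other 39 tested miR156 names, 35 had positive values with none called under TMM, and 35 were called higher with the library totals. At an unadjusted p under 0.05 edgeR had 23 of the 39, the DESeq2 test called 35 and limma-voom 0. With 1 row per distinct count pattern, also under TMM, 19 of 23 miR156 patterns were called higher and 1 lower. Several of these patterns are near-multiples of each other, so the 19 are not separate measurements. In the hot libraries mir156k-5p had 799, 1612 and 1877 counts and mir156j-5p 1599, 3226 and 3756.

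In total 58 of 253 names passed adjusted p 0.05 in edgeR's quasi-likelihood test, 18 higher and 40 lower, and they came from 12 families and 46 distinct count patterns. The split moved with the scaling and with single libraries. DESeq2 size factors gave 15 higher and 16 lower, the DESeq2 test 64 and 40, no filter 51 and 15, column sums without composition factors gave 18 and 59, and the deposited library totals gave 86 and 1. The median log2 fold change was 0.00588 under TMM and 0.99 with the library totals, so values under TMM are relative to that shift. In both of these scalings 18 names were called higher and 1 lower, while 25 of the 40 names lower under TMM had positive values with the totals. Without normal library 2, 13 were higher and 13 lower, without hot library 1 64 and 56, without hot library 3 39 and 23, and without the miR156 names 15 and 10.

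**Figure D1:**
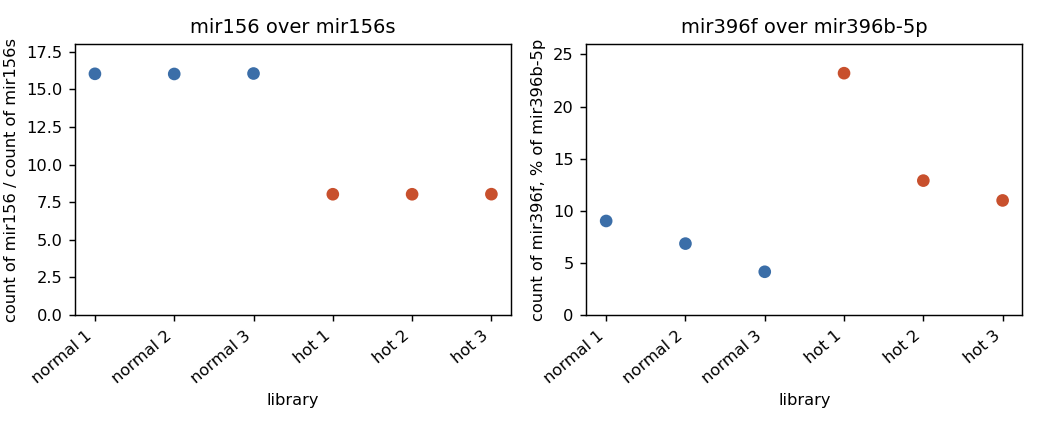
Ratio of counts of 2 names of a family in each library: mir156 over mir156s on the left, and mir396f as a percent of mir396b-5p on the right, with normal libraries in blue and hot libraries in red. The left ratio sits at 16 in the normal and 8 in the hot libraries, and the right one lies between 4.16 and 9.03 in the normal and between 11 and 23.2 in the hot libraries.

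Counts were also summed by family, with identical rows added once. Families had a TMM fit of their own, so family values are not on the scale of name values. The only row of miR5504 had -2.67 among names and -2.30 among families. Of 32 families, 11 passed the threshold, 7 higher and 4 lower in the hot libraries. The miR396 sum went from 52900 ± 5735 to 165900 ± 22620 CPM (log2 fold change 1.65, SE 0.14, adjusted p = 0.000279). It was called in all 18 other settings that were run. Also higher were miR394 (1.82, SE 0.56, adjusted p = 0.0437), miR5144 (1.44, SE 0.33, adjusted p = 0.0164) and miR1432 (1.36, SE 0.40, adjusted p = 0.0434). In the edgeR fit of names under TMM, no name of miR394, miR5144, miR1432 or miR384 was called. There mir5144-5p had 1.08 (adjusted p = 0.106), mir1432-5p 0.95 (adjusted p = 0.147) and mir384-5p 1.43 (adjusted p = 0.0873). The miR398 sum was higher too (adjusted p = 0.0405), resting on 14 summed counts in normal library 3 and 0 in normal libraries 1 and 2, against 42, 140 and 98 in the hot libraries. These are multiples of 1 row, mir398a-3p, which had 0, 0 and 1 against 3, 10 and 7 counts. The call of miR1432 was lost with sums of distinct patterns (adjusted p = 0.0502), with column sums alone, without a filter and when any library other than normal library 3 was left out. The call of miR394 was lost with column sums alone and without normal library 1, normal library 2, hot library 2 or hot library 3. That of miR5144 was lost with DESeq2 size factors, with column sums alone, without a filter, in the DESeq2 test and without normal library 2, hot library 2 or hot library 3. That of miR398 was lost with column sums alone and when any library other than normal library 3 was left out. With sums of distinct patterns miR398 did not pass the filter and was not tested. The miR384 row (1.80, adjusted p = 0.0437) is identical to the smallest miR394 row, so it adds no reads to those of miR394. The call of miR384 was lost where that of miR394 was, and also without a filter and in limma-voom. All miR394 names are whole multiples of that same row, so the miR394 sum rests on its reads alone. The miR394 family targets an F-box transcript of meristem maintenance. The miR156 sum was higher by 0.48 (SE 0.09, adjusted p = 0.00772), but was -0.02 with column sums alone.

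Lower families were miR5504 (-2.30, SE 0.41, adjusted p = 0.00772), miR3630 (-1.88, SE 0.44), miR5794 (-1.76, SE 0.31) and miR159 (-0.83, SE 0.17, adjusted p = 0.0111). With the deposited library totals 10 families were called, all but miR159, whose value was -0.23 (adjusted p = 0.445, the highest of its alternatives, which went down to 0.00208). The families miR5794 and miR3630 hold 1 row each, so their calls with the totals add no reads to those of the names. With the totals they had adjusted p = 0.0257 and 0.0297 in the edgeR fit of families. The same rows had 0.0973 and 0.0855 in the fit of names, not called, at nearly the same log2 fold changes. With column sums alone 9 families were called, 1 higher (miR396) and 8 lower. The miR166 and miR167 sums had values of -0.01 and -0.08, neither called, and miR319 -0.47, not called. All 3 were positive with the library totals. The values of their names came from the other TMM fit, so these sums do not show that the falls went away on summing. The family count depended on single libraries: it was 7 without normal library 1, 6 without normal library 2, 4 without hot library 2 and 3 without hot library 3. Without a filter none of the 4 lower families was called, and without hot library 3 only miR5504 was. Without hot library 2 miR3630 and miR159 were not called, and miR159 was not called without miR156, the most abundant family. The miR156 call was lost with DESeq2 size factors, with column sums alone, without a filter and in the DESeq2 test.

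**Figure D2:**
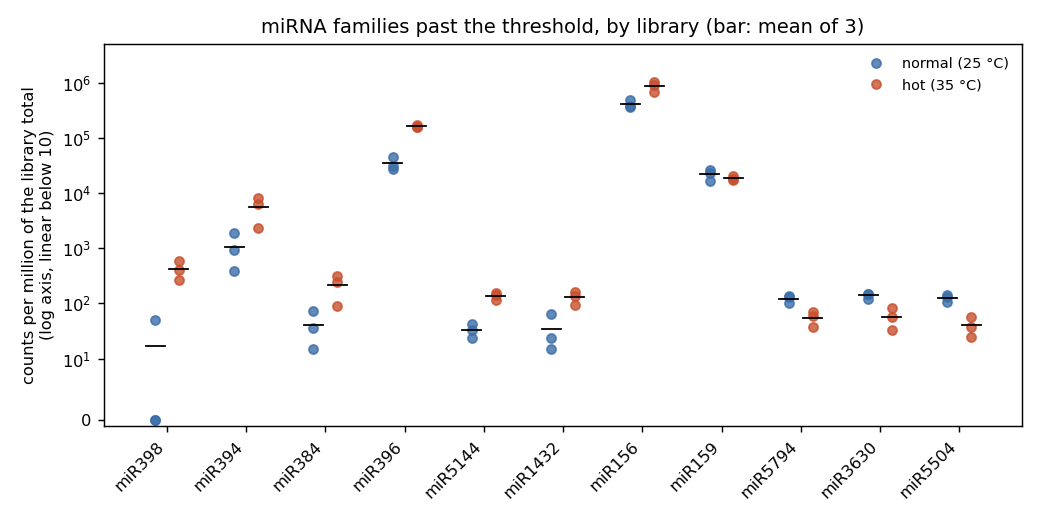
Counts as CPM of the deposited library total (log axis, linear below 10) for the 11 families past the threshold, 1 point per library and a bar at the mean of 3. The hot points of miR396 lie above all its normal points, while those of miR159, called lower under TMM, overlap its normal points on this scale.

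**Figure D3:**
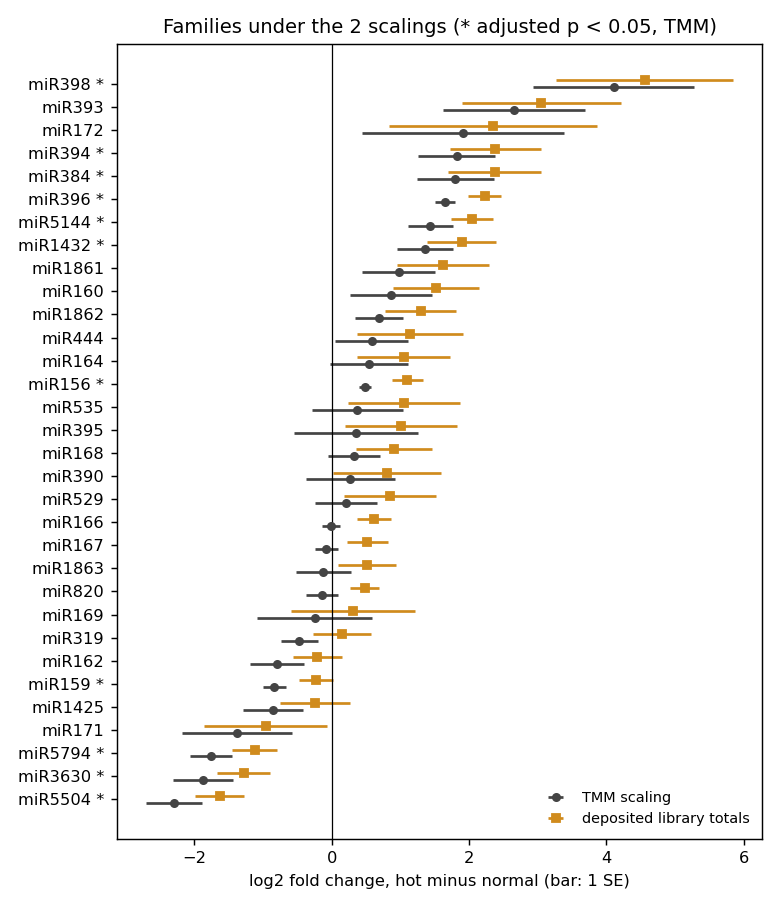
Log2 fold change, hot minus normal, of the 32 tested families (bars: 1 SE) under TMM scaling (circles) and with the deposited library totals (squares); an asterisk marks adjusted p under 0.05 with TMM. The squares lie to the right of the circles, so that miR166, miR167, miR169, miR319, miR820 and miR1863 are below 0 by TMM and above 0 with the totals.

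Of the lists fixed before the data were examined, 9 could be tested and 3 passed camera with the preset correlation. None of the 9 passed with an estimated correlation, and 3 passed at adjusted p under 0.05 with fry: developmental transcription factors, silencing machinery and copper responsive. The squamosa and phase change list (46 tested names of miR156, miR529 and miR535) was called up, with a median log2 fold change of 0.21 (adjusted p = 0.00203, but adjusted p = 0.91 with an estimated correlation and 0.242 with fry). Over its alternatives the adjusted p went from 5.16e-05 to 0.946. No member was called higher and 1 was called lower, mir156, both over all names and adjusted over the list alone. Without hot library 1, 34 were higher and 2 lower, without hot library 2, 3 and 1, and without hot library 3, 23 and 1. The DESeq2 test had 35 and 1, and 1 row per distinct pattern had 19 and 1. The developmental transcription factor list (93 names) was called down, with a median of -0.38 (adjusted p = 0.00234, and adjusted p = 0.622 with an estimated correlation). Its 14 names called higher were all of miR396 and its 26 called lower were of miR159, miR166 and miR319, so its members moved both ways. Adjusted over the list alone, 15 were higher and 38 lower. Over all names, leaving out 1 library gave 12 higher and 10 lower (without normal library 2) to 14 and 37 (without hot library 1). With 1 row per distinct pattern its adjusted p was 0.102, and over all its alternatives it went from 5.22e-05 to 0.946. The copper responsive list held 3 tested names, all miR398 rows from the same reads, and all 3 were higher, also adjusted over the list alone (adjusted p = 0.00987, and adjusted p = 0.622 with an estimated correlation).

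The other lists were not called. In the auxin related list, 1 of 53 names was higher (mir393b-3p) and 8 were lower (all miR167), or 1 and 6 adjusted over the list alone. The number lower was 0 without normal library 2, normal library 3 or hot library 3, 1 without hot library 2, 5 without hot library 1 and 10 without normal library 1. Its median of 0.12 and mean of 0.08 were positive while camera gave the direction down (adjusted p = 0.759). Its most abundant names, mir167a and mir167c, had -0.28 (adjusted p = 0.144) and -0.42 (adjusted p = 0.0412). In the silencing machinery list, miR162 and miR168, whose targets are Dicer-like and Argonaute transcripts, 0 of 14 names passed, over all names or adjusted over the list alone. The median was -0.70 (adjusted p = 0.172), and fry gave adjusted p = 0.0378, within a range of 0.034 to 0.946 over its alternatives. The names mir162 and mir162a had values of -1.13 each (adjusted p = 0.0926), and without hot library 1 mir162 passed at -1.74. The list moved with single libraries: without hot library 1, 7 of 14 names were lower and camera passed (adjusted p = 0.0351), and without normal library 2 none was lower while camera passed (adjusted p = 0.034). With an estimated correlation camera passed in neither case (adjusted p = 0.366 and 0.808). At an unadjusted p under 0.05 edgeR had 5 names of this list, all lower, while the DESeq2 test called 3 and limma-voom 5, also lower. None of the 16 sulfate and phosphate names (all miR395, adjusted p = 0.911) passed in edgeR over all names, adjusted over the list alone or at an unadjusted p under 0.05, nor in the DESeq2 test or limma-voom. The identical rows mir395a and mir395b had 54, 72 and 18 against 108, 19 and 90 counts. They are near-multiples of mir395a-3p, which had 3, 4 and 1 against 6, 1 and 5 counts.

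The monocot families list had 0 of 13 names past the threshold, also adjusted over the list alone (adjusted p = 0.223). At an unadjusted p under 0.05 edgeR had 1, lower, and the DESeq2 test and limma-voom called 0. Its leading names mir1862d and mir529-3p had 0.31 (SE 0.18) and 0.02 (SE 0.21). With the deposited library totals mir1862d, mir1862e, mir1432-5p, mir444a, mir444b, mir444b-2, mir444c-2 and mir444c-3p were called higher (adjusted p = 0.0185 to 0.0485). No name of the monocot list was called lower there. Of 222 names conserved across flowering plants, 18 were higher and 35 lower, or 18 and 36 adjusted over the list alone (adjusted p = 0.759). The DESeq2 test had 60 and 35 and edgeR at an unadjusted p under 0.05 had 53 and 56, while without hot library 1 the numbers were 63 and 51, without normal library 2 13 and 11, and without hot library 3 39 and 21. Of 31 lineage restricted names, 0 were higher and 5 lower, or 0 and 3 adjusted over the list alone (adjusted p = 0.759). The DESeq2 test called 4 of these higher and limma-voom 0, and 5 were higher at an unadjusted p under 0.05 in edgeR. With the deposited library totals names of miR1861, miR1862, miR1432, miR384, miR444 and miR5144 were called higher and only mir5504 lower. The miR384 row is identical to a row of miR394, a family of the conserved list. Under TMM the number lower was 2 without normal library 1, normal library 2 or hot library 3. Both complementary lists had medians close to 0, of 0.00588 and 0.00312, where camera gave the direction down for the first. The lineage restricted mean was -0.07 where camera gave the direction up. The most abundant names of the latter, mir1862d and mir1861b, were not called under TMM, and mir1861b had a value of 1.08 (adjusted p = 0.0951). With the library totals both were called, mir1861b at 2.06 (adjusted p = 0.0035) and mir1862d at 1.28 (adjusted p = 0.0185). Of the suspected structural RNA fragments only mir894 was present, with 1 count in normal library 1, too few for a test.

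Library composition was compared to describe depth and dominance by a few names. The deposited sum was 61.41% ± 10.7 of the library total in the normal and 133.3% ± 23.8 in the hot libraries (SD, n = 3 each, exact permutation p = 0.1, adjusted p = 0.175). The share of 3p names among names with an arm was 15.64% ± 0.371 and 8.747% ± 0.498 (exact p = 0.1, adjusted p = 0.175). Outside miR156, miR159 and miR396 it was 72.1% ± 3.82 and 67.4% ± 4.86 (exact p = 0.3). The most abundant name took 9.309% ± 0.084 and 9.733% ± 0.271, and the 10 most abundant took 50.56% ± 0.474 and 48.88% ± 1.32 (exact p = 0.1 each, adjusted p = 0.175). The 10 include mir156, at 16 times mir156s in the normal and 8 times in the hot libraries. The lower share of the 10 is therefore no measure of less dominance. The miR156 family took 75.55% ± 0.7 and 75.01% ± 2.06, and conserved families 99.27% ± 0.0488 and 99.25% ± 0.072 (exact p = 0.8 each). The number of names above 0 was 467 ± 49.8 and 479.3 ± 18.2 (exact p = 0.7). An exact p of 0.1 is the smallest that 3 against 3 libraries allow, so none of these tests could pass 0.05.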

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

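Scaling by the deposited library totals, 1 row per count pattern, leaving out miR156 and other family sums were chosen after seeing the data. The number of called names, 58, was 31 with DESeq2 size factors, 104 in the DESeq2 test, 25 without the miR156 family and 120 at adjusted p 0.1, and leaving out 1 library gave 26 (without normal library 2) to 120 (without hot library 1). The number of called families, 11, was 5 without a filter, where 113 families were tested, and leaving out 1 library gave 3 (without hot library 3) to 12 (without normal library 3). Families summed over all names gave 11, the same 11 in the same directions, and distinct patterns gave 9. Called lists, 3, fell to 0 with an estimated correlation, to 1 with 1 row per pattern and to 0 with both; with pattern rows the copper responsive list had too few names for a test. The cause of these changes was not tested.

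The replicate numbers were checked for pairing: deviations of libraries with the same number correlated at 0.417, -0.151 and 0.00884, so they share only a number, and only hot library 1 and normal library 1 correlated best with their own number. With the replicate block 111 names (62 higher, 49 lower), 9 families and 2 lists were called, with 34 phase change names higher. The names mir398b and mir1861h and the miR156 and miR398 sums were not called. With an estimated correlation camera called neither list there (adjusted p = 0.997 for phase change and 0.914 for developmental transcription factors).

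Some directions turned. With the library totals, mir156 had 0.1905 (0.1905 also with pattern rows), mir167a 0.6787 (0.6788) and mir167c 0.5431 (0.5434); without miR156, mir167a had 0.0742. With column sums alone, mir395a and mir395b had -0.08678, mir529-3p -0.1221 and miR156 as a family -0.01893. With limma-voom, mir395a and mir395b had -0.2008. Leaving out 1 library gave -0.9835 to 0.54 for mir395a and mir395b and -0.06639 to 0.1384 for mir529-3p. Lists that turned, none called, had adjusted p of 0.894 (sulfate and phosphate) and 0.406 (lineage restricted) with fry, and leaving out 1 library 0.251 to 0.97 (auxin related), 0.0694 to 0.96 (sulfate and phosphate) and 0.322 to 0.96 (conserved, and lineage restricted).

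The differences in composition kept within 1 SD when 1 library or the most abundant name was left out, but 3 near 0 turned sign: share of the miR156 family from -0.5372 to 0.5806 (without hot library 1), number of names above 0 from 12.33 to -8.667 (without normal library 1; 39.83 without normal library 3) and share of conserved families from -0.02545 to 0.001207 (without normal library 3) and 0.005644 (without hot library 1). With 1 row per pattern, the difference in the conserved share turned to 0.07233 and in the 3p share -10.23 percentage points. All 14 miR396 names kept their direction and call with the library totals, and mir5504 was called in all 18 settings.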

Other observations

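All tests here were chosen after the result was seen, except the count of splits. Some names not called had uneven counts over the libraries of a group. The miR408 names, in the copper responsive list but too low to test, had counts only in hot library 1 (38 under mir408 and 14 under mir408-3p, with 0 in the other 5 libraries), apart from 2 counts of mir408-5p in hot library 3. The smallest row of the hot library 1 pattern, mir408a-3p, held 2 counts, so the larger values repeat few reads. The name mir171a had 123 counts in normal library 3, against 9 and 13 in the other normal libraries and 14, 20 and 35 in the hot ones. The name mir390a had 24, 0 and 72 counts in the normal and 12, 60 and 48 in the hot libraries. These are multiples of the row mir390-5p, which had 2, 0 and 6 against 1, 5 and 4 counts. The 11 miR394 names had values of 1.43 to 1.45 under TMM and none was called singly, while their sum was. All 11 are multiples of 1 count pattern, so the sum adds no reads. The sum was scaled in the family fit and adjusted over fewer tests. With the deposited library totals the names had 2.375 to 2.384, and all 11 were called.

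Within miR1861, mir1861b and mir1861h moved apart. The log2 ratio of their counts was 1.54 ± 0.175 in the normal and 5.34 ± 1.9 in the hot libraries (SD, n = 3 each, exact permutation p = 0.1, the smallest possible), and hot library 1, with 1 count of mir1861h, had a ratio of 185. Of 2 arm ratios, mir166a-5p over mir166a-3p did not show such a difference (exact p = 1), and mir396a-3p over mir396a-5p went from -5.39 to -6.42 on the log2 scale (difference -1.03, exact p = 0.2).

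For single names, the real grouping gave 58 calls and the highest of the other splits 0; for families it was 11 against 0. In each case 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

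Among the 39 tested miR156 names other than mir156, 35 had positive values under TMM and none was called. Below 0 were mir156f-3p (-1.28), mir156g-3p (-0.84), mir156c-3p and mir156e-3p (-0.37 each). The name mir156 was the only one of its family called lower in hot libraries under TMM. Its counts over those of mir156s lay within 0.039 of 16 in the normal and 8 in the hot libraries, which is consistent with a different number of database entries being added under this name in the 2 groups. A sequence of its own that falls at 35 °C is argued against by the range of that ratio within a group, at most 0.18% of its mean, below counting error of separate reads. The file gives no sequences, so how entries were added stays open.

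Most names were higher in hot libraries per deposited library total. If a few abundant miRNAs took the gain, names outside miR156 and miR396 would have stayed near 0, but their median was 0.635, and 8 of 9 pairs of 1 hot and 1 normal library were above 0.1. Hot library 1 against normal library 3 was at -0.0579, so this stays open. Fewer other reads (adapter dimers, fragments or other small RNA) in the totals of hot libraries could give the 71.85 percentage points between the groups in deposited sum per total, and a biological rise of miRNA at 35 °C cannot be told apart from it, since what the total counts is not stated.

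The miR396 names rose by different amounts. The counts of mir396f were 9.03, 6.86 and 4.16% of mir396b-5p in the normal and 23.2, 12.9 and 11% in the hot libraries (log2 difference 1.22, exact permutation p = 0.1). The share of each of the 12 called patterns in their sum would be constant if a single pool of reads stood under all of them. Its range over the 6 libraries had a lower quartile of 26.8% of the mean (8.91 to 130% over the patterns), which argues against such a pool for the set. A different number of entries per group would leave the share constant within a group, and the smaller group range had a lower quartile of 7.43% and a median of 10.7% (1.1 to 57%), over 10% in 7 of 12 patterns. This does not settle it for the set, so uneven entries may account for part of the spread. The quartile and the 10% bound were chosen after these ranges were seen. A hypothesis also left open is that miR396 members with different sequences respond differently to temperature; reads shared between them were not separated here.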
